A study of Homo sapiens with 2 samples.

How the data were processed

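DamIP-seq libraries were made from MCF-7 cells transfected with DamK9A alone or with DamK9A fused to human ERα, 1 library each. Per the labels' protocols, cells meant for ligand treatment were kept at least 3 days in phenol red-free medium with 10% charcoal-stripped serum, then received 100 nM beta-estradiol for 24 hours. DNA pulled down with an antibody against N6-methyladenosine was made double-stranded with Klenow enzyme and random hexamers before library construction, per the labels' protocols. Random priming copies each fragment from internal positions, so read ends need not mark fragment ends, and any adenine-methylated DNA in the cells, of whatever origin, can enter the libraries.

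The submitters' processing notes name Bowtie as a tool and NCBI36 as the genome build; the version and settings of the aligner are not given in the sources used here. The deposited peak list has 5 columns and no header: chromosome, start, end, a peak name and a score. The peak names show that the authors called the peaks with MACS, a peak caller that compares reads in a treated library with a control library under a Poisson model. The list was called on the pair of libraries, per the deposited file, so it has no value per library and no replicate. The deposited score was read as −10 times the log10 of the p-value, since it was never below 50, had its highest value at exactly 3100 and took many values that equal Poisson tail probabilities of whole read numbers. Its scale is therefore read from the values, not stated. How duplicate reads and reads with several alignments were treated is not given in the sources used here, and either would change scores in repeats. The start positions were taken as counting from 0, as the format has it, and are printed counting from 1.

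From this list, widths, score quantiles, peaks per chromosome and per window of 5 Mb, distances between neighbouring peaks and clusters were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Density was taken over the span from the first to the last peak of each chromosome, with 95% exact Poisson intervals. The span includes the centromere only where that lies between these peaks, and it leaves out the sequence before the first peak. The first peak lay furthest in on chromosomes 14, 15, 13 and 22, at 20068963, 19349957, 18455617 and 15685925. Spacing was tested against 1000 random placements over each chromosome's span. Clusters were chains of at least 3 peaks with centres within 10 kb of the next. The single Poisson mean behind the most common scores was fitted by least squares to the scores that it matched, with a tolerance of 0.015. Widths of the named peaks were compared by an exact permutation test over the 20 peaks, and shares between windows with at least 20 peaks by 100000 permutations of windows. Each test across peaks asks about positions or scores within this list, not about a difference between replicated conditions.

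The rule for the named items was set before the data were examined: the 20 peaks with the highest score (ties by width, then position), the 5 clusters with the most peaks, the widest and the narrowest peak and the chromosomes with the highest and lowest density. Clusters with equal numbers of peaks were ordered by their highest score, which the rule had not fixed. The windows of 5 Mb, the fit of the Poisson mean and the width comparison were added after the list had been seen.

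The planned comparisons that need sequence or gene positions in NCBI36 were not made, since no genome or annotation of that build was used here: peaks relative to genes, GATC sites and estrogen response elements in peaks, the gene lists (estrogen-induced and estrogen-repressed genes, luminal regulators, receptor coregulators, cell cycle genes, housekeeping genes, basal, liver and muscle genes and olfactory receptors) and the test of peak number against chromosome length. The available gene table is for GRCh38, and coordinates were not converted.

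The spacing test and the fit were tested on simulated data. A simulated list of 14840 uniformly placed peaks gave a ratio of 0.99 to random placement, and the list with 1000 neighbours planted at short distance gave 1.95. In simulated scores with Poisson means of 0.1 and 0.3, the fit returned 0.10 and 0.30, and it assigned 29.4% and 31.1% of the scores to the mean where 29.3% and 30.9% had been drawn from it. The alternatives tried were a score of at least 100, the upper part of the scores from the median, joining of peaks within 1 kb, removal of clustered peaks, other chaining distances, distances between edges and random placement inside 1 Mb blocks.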

Results

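DamIP-seq was used to map where estrogen receptor alpha (ERα) sits on the genome of MCF-7 cells, a human breast cancer line that expresses the receptor and grows in response to estrogen. In DamIP, a mutant of the bacterial DNA adenine methyltransferase Dam is fused to a protein of interest, the fusion methylates adenines in the DNA near the places where that protein binds, and the methylated DNA is pulled down with an antibody against the modified adenine. The 2 libraries came from cells transfected with the mutant enzyme alone (DamK9A, 1 library) and from cells transfected with its fusion to human ERα (DamK9A-hERalpha, 1 library). The labels' protocols give beta-estradiol at 100 nM for 24 hours for cells meant for ligand treatment, and both groups are taken as such here. The data analysed here were 1 list of peaks called in the fusion library over the enzyme-alone library. The list holds no read counts, so the depth of either library is unknown, and with 1 library per group no difference between the groups could be set against replicate error.

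The comparison of the fusion with the enzyme alone asks where ERα directs methylation beyond the background of free Dam. The fusion library was enriched over the enzyme-alone library at 14840 places, which lay on all 24 chromosome names in the list and together covered 6237 kb. The peaks were short, with a median width of 397 bp and quartiles of 316 and 480 bp. No peak overlapped its neighbour. The authors' peak score, which is read here as −10 times the log10 of the peak's p-value and belongs to the peak rather than to a sample, had a median of 98.3, with quartiles of 78.5 and 148 and a lowest value of 50.02. A score of at least 100 was reached by 7297 peaks (49.2%) and a score of at least 1000 by 63. Wider peaks tended to score higher across the list (Spearman's rho 0.23, 95% bootstrap interval 0.21 to 0.24 over peaks, which are not independent replicates). The narrowest peak, 161 bp, was at chromosome 3 from 23743825 to 23743985 with a score of 148.46. The widest, 4969 bp, was at chromosome Y from 11939219 to 11944187 with a score of 521.82. All positions are in build NCBI36 and count from 1.

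The 20 highest-scoring peaks fell on 7 chromosomes, with 6 on chromosome 20, 6 on chromosome 6, 3 on chromosome 17, 2 on chromosome 1 and 1 each on chromosomes 3, 8 and 15. Gene names are not given for them, because no gene annotation of this build was used here. The score reached its highest value, 3100, at 6 peaks, so their order among themselves is not resolved. Of these, 1 was on chromosome 20 from 45264234 to 45265295 (1062 bp) and 1 on chromosome 3 from 151937443 to 151938359 (917 bp). The other 4 were on chromosome 6. Below them came 2 peaks on chromosome 20, from 55989336 to 55990094 with a score of 2774 and from 47494240 to 47495037 with a score of 2670. The next were on chromosome 17 from 62359830 to 62361034 (score 2420) and on chromosome 15 from 71806133 to 71806993 (score 2186). Chromosome 20 held another 3 named peaks, which began at 51657921 (score 2044), 46621971 (score 1944) and 45627233 (score 1816). Chromosome 17 held another 2, which began at 52789757 (score 1979) and 54423663 (score 1917). The named peak on chromosome 8 ran from 143832517 to 143833724 with a score of 1980.5, and the 2 on chromosome 1 began at 148802943 (score 1882) and 110294632 (score 1761).

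The 6 named peaks of chromosome 6 lay together within 257 kb, from 152205370 to 152461923. Scores of 3100 were given to the peaks that began at 152205370, 152306876, 152457080 and 152461436, and the other two, at 152243359 and 152423682, scored 1900.0 and 1875. The stretch held 8 peaks in all, and the remaining 2 scored 737 and 62.5. A further peak, 1484 bp wide with a score of 643, began outside the stretch, at 152169839. The 6 named peaks were narrower than the other 14 named peaks, with widths of 458 ± 81 bp (SD, n = 6 peaks) against 872 ± 205 bp (SD, n = 14 peaks). This difference of −414 bp, compared only after the widths had been seen, had an exact permutation p of 0.000258 (two-sided, over all 38760 ways of choosing 6 of the 20 peaks). The widest of the 6 was 604 bp and the narrowest of the 14 was 563 bp. The 5 Mb on each side of the stretch held 40 peaks, or 4.0 per Mb, a ratio to the density of chromosome 6 of 1.05 (95% exact Poisson interval 0.75 to 1.44, counting error only).

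**Figure D1:**
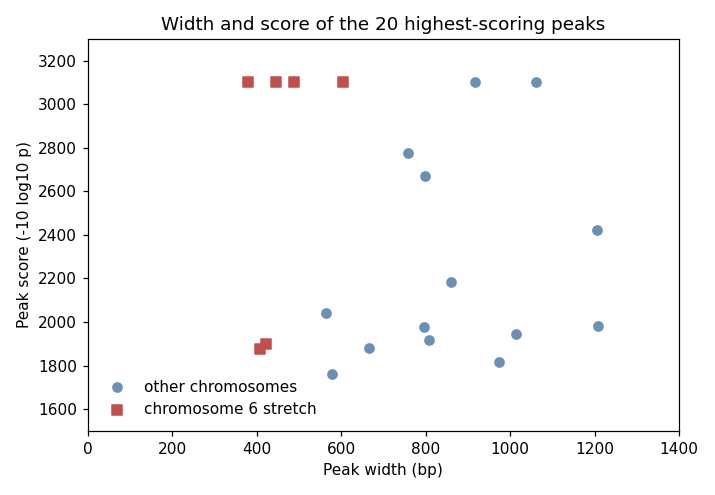
Peak width (x axis, bp) and the authors' peak score (y axis, −10 log10 p, which does not start at 0) of the 20 highest-scoring peaks, with 1 point per peak and squares for the chromosome 6 stretch. The 6 squares lie between 379 and 604 bp, while the 14 peaks of other chromosomes lie between 563 and 1208 bp.

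Chromosomes 20 and 17 carried the most peaks for their size. Chromosome 20 had 750 peaks, or 12.1 per Mb of the span from its first to its last peak (95% exact Poisson interval 11.2 to 13.0), and chromosome 17 had 855, or 10.9 per Mb (10.2 to 11.7). The density over all spans was 5.0 per Mb, so chromosome 20 was at 2.41 times and chromosome 17 at 2.19 times that level. Chromosome 19 came next with 7.59 per Mb (6.92 to 8.30), and its interval did not reach those of chromosomes 17 and 20. The lowest densities among the autosomes were on chromosome 18, with 2.55 per Mb (2.20 to 2.93), and chromosome 4, with 2.79 per Mb (2.56 to 3.03). Chromosome X had 303 peaks, or 2.01 per Mb (1.79 to 2.25). Chromosome Y had 12 peaks, or 0.26 per Mb (0.14 to 0.46), and 7 of them lay in a single cluster of 27.6 kb. Neither the presence of chromosome Y in these cells nor the placement of reads there was checked. The peaks listed on Y may therefore not mark binding on that chromosome. The intervals of all these densities cover counting error only and treat peaks as independent, which neighbouring peaks are not. MCF-7 is aneuploid, and the chromosomes named before the data were examined as carrying reported gains (17 and 20) ranked 2 and 1 of 24. Those named for reported losses (4 and 18) ranked 21 and 22. Chromosomes named for neither lay next to them. Chromosomes 19, 22 and 16 ranked 3, 4 and 5, and chromosomes 13 and 5 ranked 20 and 19. The spans of chromosomes 22 and 13 began only at 15685925 and 18455617, which raises their densities against chromosomes whose spans begin near the start. Density was compared neither with copy number nor with gene density, so the ranks do not show which they follow. Median scores were 97.1 on chromosome 20 and 95.2 on chromosome 17, against 98.3 for the whole list. Chromosomes 17 and 20 together held 15 of the 63 peaks with a score of at least 1000 (23.8%) and 1605 of all peaks (10.8%).

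**Figure D2:**
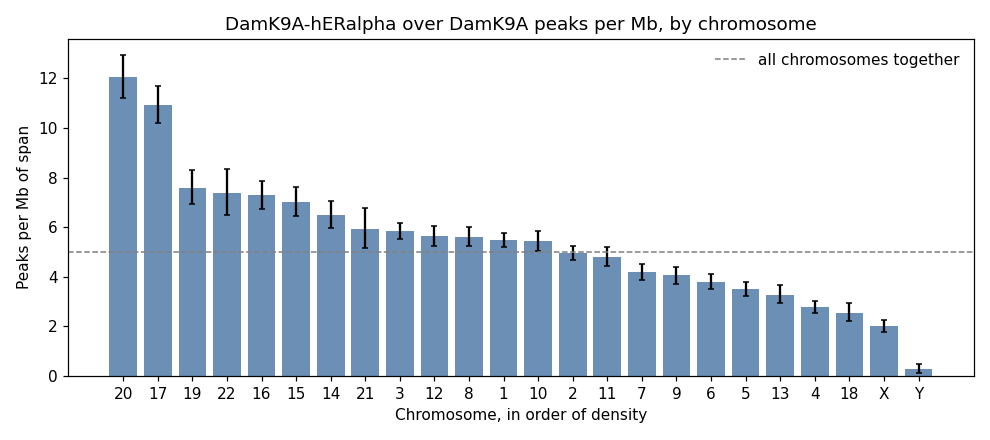
Peaks per Mb of the span between the first and last peak of each chromosome (y axis) for the 24 chromosomes in order of density (x axis). Bars are the densities, whiskers the 95% exact Poisson intervals and the dashed line the density over all spans (5.0 per Mb); chromosomes 20 and 17 stand at 12.1 and 10.9.

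Part of the excess on these chromosomes lay in a few stretches. In windows of 5 Mb, the median was 19 peaks over the 590 windows that held any. The window from 45 to 50 Mb on chromosome 20 held 212 peaks, 11.2 times the median. It was followed by the window from 55 to 60 Mb on chromosome 17 with 145, the window from 200 to 205 Mb on chromosome 1 with 122 and the window from 60 to 65 Mb on chromosome 3 with 121. The 10 densest windows also took in 50 to 55 and 60 to 65 Mb on chromosome 17 (110 and 85 peaks), 50 to 55 and 55 to 60 Mb on chromosome 20 (90 and 87), 125 to 130 Mb on chromosome 8 (109) and 40 to 45 Mb on chromosome 21 (85). Together they held 1166 peaks, or 7.86% of the list. Outside its 3 dense windows, chromosome 17 still had 515 peaks, or 8.14 per Mb (95% exact Poisson interval 7.46 to 8.88), and chromosome 20 had 361, or 7.65 per Mb (6.88 to 8.48). These are 1.63 and 1.53 times the density over all spans, and 42.9% and 28.5% of the excess of peaks over that density lay there. Peaks in these windows had a median width of 440 bp and a median score of 95.2, against 394 bp and 99.0 elsewhere.

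**Figure D3:**
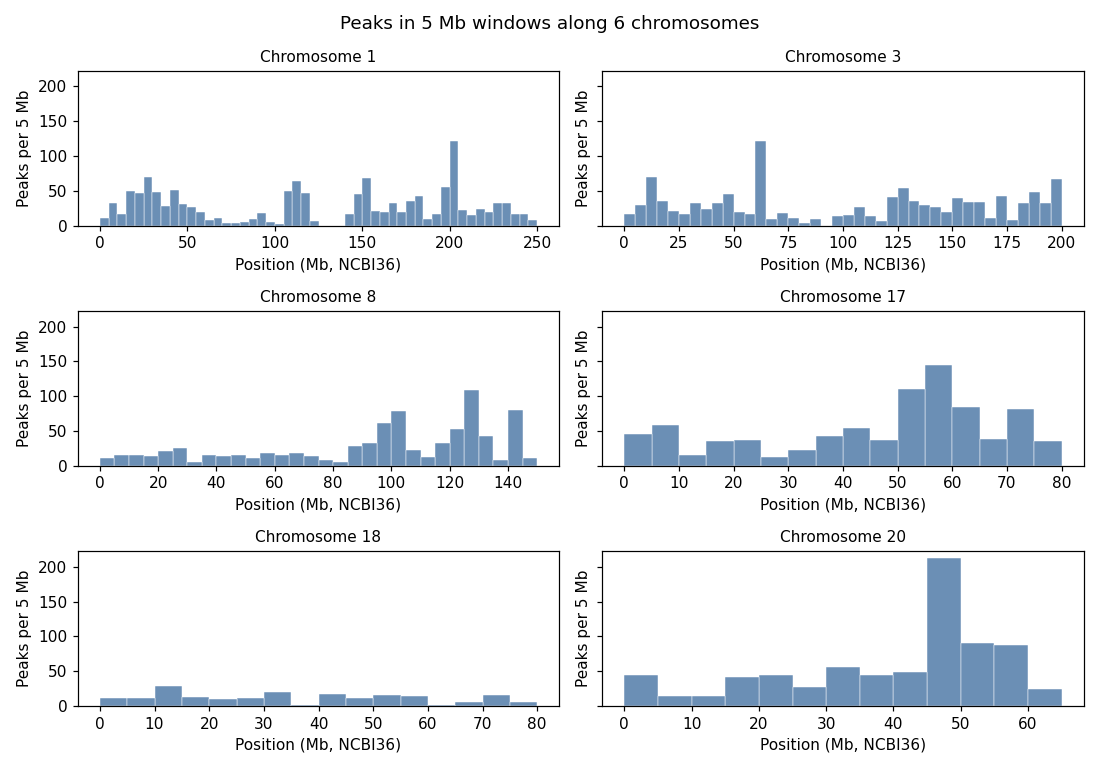
Number of peaks (y axis) in consecutive 5 Mb windows along chromosomes 1, 3, 8, 17, 18 and 20 (x axis, position in Mb, build NCBI36), 1 bar per window. The tallest bar, 212 peaks, is at 45 to 50 Mb on chromosome 20, and single tall bars of 122 and 121 peaks stand at 200 to 205 Mb on chromosome 1 and 60 to 65 Mb on chromosome 3.

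Peaks lay closer to each other than random placement gave. The next peak was within 10 kb for 15.1% of peaks, against 5.65 ± 0.18% (SD over 1000 random placements that kept each chromosome's number of peaks and span), a ratio of 2.67. Within 100 kb the share was 58.2% against 42.8 ± 0.30%, a ratio of 1.36. Both had a one-sided permutation p of 0.001, the smallest that 1000 placements can give. When each 1 Mb block kept its own number of peaks, so that only spacing inside blocks could differ, the ratios were 1.62 and 1.06, also with permutation p of 0.001.

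Chaining peaks whose centres lay within 10 kb of the next gave 340 clusters of at least 3 peaks, with 1169 peaks (7.88% of the list). Chromosome 20 had 47 of these clusters, chromosome 17 had 34 and chromosome 3 had 33, and 94 of the 340 were centred in the 10 densest windows. The cluster with the most peaks had 10 and ran from 54515571 to 54554654 on chromosome 17, with a highest score of 303.43. It was followed by a cluster of 8 peaks on chromosome 20 from 46260818 to 46290713 (highest score 312.86). There were 2 clusters of 7 peaks, 1 on chromosome 20 from 45602112 to 45635436, which contains a named peak of score 1816, and 1 on chromosome Y from 11919688 to 11947335, where the highest score was 743.75. Of the 12 clusters of 6 peaks, the one with the highest score (719.21) was on chromosome 17 from 54786078 to 54805721.

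The scores did not vary smoothly. In 3449 peaks (23.2%) the score equalled, within 0.015, −10 times the log10 of the Poisson probability of more than a whole number of reads at a single mean of 0.150 reads. At 1000 other means the median number of such matches was 19. The highest was 922 once means very close to the fitted one were left out. The most common of these scores were 78.49 (908 peaks, probability of more than 5 reads), 95.18 (866 peaks, probability of more than 6 reads) and 112.45 (645 peaks, probability of more than 7 reads). These peaks were narrower than the rest, with a median width of 269 bp and quartiles of 238 and 294 bp, against a median of 435 bp and quartiles of 374 and 518 bp for the other 11391.

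**Figure D4:**
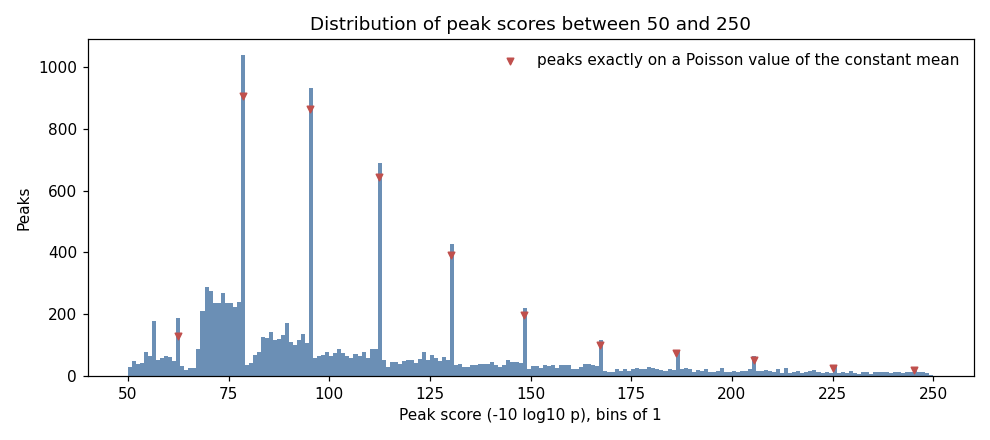
Number of peaks (y axis) by the authors' peak score (x axis, −10 log10 p, bins of 1, from 50 to 250). Triangles mark the number of peaks whose score equals a Poisson value of the single mean 0.150; the tallest spikes are at 78.49, 95.18 and 112.45.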

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

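Of 71 recomputed values, 12 moved beyond the limit for their kind, a factor of 1.5 for counts and the 95% interval of the main value for others without a test. The other 59 stayed within it, or on the same side of the threshold where there was a test. Raising the score minimum to 100 left 7297 peaks, with a median width of 429 bp, a median score of 148.46 and a correlation of width with score of 0.39; joining peaks within 1 kb moved the medians to 403 bp and 100.26. Without peaks in clusters, the density relative to all spans fell to 2.01 on chromosome 20 and 1.98 on chromosome 17, and their ranks stayed 1 and 2 under each alternative run. Clusters numbered 70 at a score of at least 100, 71 among the upper part of the scores, 160 when chained at 5 kb and 1297 when chained at 50 kb; fewer peaks or shorter distances give fewer chains by construction. The spacing ratio within 10 kb ranged from 1.62 to 3.01 and that within 100 kb from 1.06 to 1.66, each with a permutation p of 0.001; the lowest of both came from placement inside 1 Mb blocks. Leaving out the chromosome 6 stretch and the peaks wider than 2 kb, chosen after seeing the data, left 14824 peaks and 338 clusters. Alternatives for gene positions, sequence elements, gene lists and chromosome length were not run, since no genome or annotation of the build was used here. No paired analysis was possible because each group has 1 library. The list holds no counts, so the depth of the libraries and what it limits cannot be read from it directly. If the Poisson reading of the scores holds, many calls rest on few reads. The 3 most common scores, in 908, 866 and 645 peaks, correspond to the Poisson probabilities of more than 5, 6 and 7 reads at the mean of 0.150.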

Other observations

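The tests in this part of the share of scores at the constant Poisson mean, of the widths on chromosome 6 and of the density beside that stretch were chosen after the results were seen. High-scoring peaks were spread beyond the chromosomes named for gains. Chromosome 8 held 9 of the 63 peaks with a score of at least 1000 (14.3%), as many as chromosome 20, while its density of 5.62 peaks per Mb compares with 5.0 over all spans. This density was uneven, with 109 peaks at 125 to 130 Mb and 80 at 140 to 145 Mb (highest scores 1231 and 1980.5). Scores above 1000 also occurred in its windows from 10 to 15 and 45 to 50 Mb, with 15 peaks each (highest 1481 and 1699). Chromosome X, with the lowest density apart from Y, held 2 of them. On chromosome 21, the window from 40 to 45 Mb held 85 of the chromosome's 220 peaks, with a highest score of 1036. On chromosome 3, the window from 60 to 65 Mb held 121 peaks but no score above 549.0.

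The chromosome 6 stretch combined 6 of the 20 highest scores with narrow peaks, and the construct in the fusion library carries the coding sequence of human ERα. The gene for ERα, ESR1, is on chromosome 6, and its coding sequence is split over 8 exons; it was chosen after its values were seen, and its position in NCBI36 was not checked against an annotation here. The 6 peaks had a median width of 434 bp, below the lower quartile of 768 bp of the other named peaks (exact permutation p = 0.000258), and differed by −333 bp on average from the 57 other peaks with a score of at least 1000 (permutation p = 0.00115). A candidate explanation is that reads came from the transfected coding sequence, whose alignments end at exon borders, and another is strong receptor binding sites. The widths support neither, since the stretch was noticed for its narrow peaks. Peaks were not matched to exons, because exon positions in this build were not used. The count of 8 peaks in the stretch is no such match, since it depends on where the stretch was taken to begin and end. It includes a peak of score 62.5 at the constant mean and leaves out the peak of score 643 beside the stretch. Exchanging the first for the second would leave 8 peaks, all with scores of at least 643. The count therefore argues neither for nor against exons. Of the 57 other peaks, 14 were no wider than the widest of the 6 (604 bp), but the narrowest was 446 bp, above the median of the 6. Both stay open. So does a gain of copies of the surrounding chromosome: the flanking density of 1.05 times that of chromosome 6 has an interval of 0.75 to 1.44, which allows a modest gain, and it bears on copies only if peak density follows them. A gain limited to the stretch was not tested.

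The 10 densest windows raise the question whether the number of peaks follows the number of DNA copies in MCF-7, where arms of chromosomes 17 and 20 are reported to be gained. The other dense windows lie on chromosomes not named for gains beforehand. Chromosomes 1 and 3 as a whole ranked 12 and 9 of 24, at 1.096 and 1.169 times the density over all spans. A gain limited to part of a chromosome could leave such ranks little changed, so they say nothing on copies of the single windows. If the constant mean of 0.150 is the genome-wide background that the peak caller uses where the control library has few reads nearby, stretches with more copies in both libraries should have fewer peaks at it. The share was 16.0% in the 10 densest windows against 23.2% in the other windows with at least 20 peaks, a difference of −7.19 percentage points (permutation of windows, two-sided p = 0.0047), and −5.05 to −6.87 points with 20 windows, 2 Mb windows or scores of at least 100 (p from 0.00644 to 0.0483). Neighbouring windows are not independent, and 6 of the 10 lie in 2 unbroken stretches, on chromosomes 17 and 20. When the 10 were shifted together along the windows with at least 20 peaks, in genome order, so that neighbours mostly stayed neighbours, 4 of 292 positions, the real one included, gave a difference as large (share 0.0137). Without the dense windows of chromosome 17 the difference was −6.52 points (permutation p = 0.0283), and without those of chromosome 20 it was −6.88 (permutation p = 0.0225). Leaving out any 1 of the 10 windows gave −6.28 to −7.87 points (p from 0.00347 to 0.0167). The windows were not alike: the share was below 23.2% in 9 of them but ran from 9.66% at 55 to 60 Mb on chromosome 17 to 24.7% at 40 to 45 Mb on chromosome 21 (95% exact binomial interval 16.0% to 35.3%), and it was 21.3% at 200 to 205 Mb on chromosome 1 and 20.7% at 55 to 60 Mb on chromosome 20. The 10 windows pooled have the lower share that more copies would give. If that reading of the mean holds, the control library more often had reads near the peaks of these windows. The share is then itself a measure of control signal, so it does not test whether binding is denser there. Peaks not at the constant mean were also wider in these windows, with a median of 461 bp against 432 bp elsewhere. Those at the mean had medians of 270 and 269 bp. The exact interval lay wholly below 23.2% at 45 to 50 Mb on chromosome 20 and at 55 to 60 Mb on chromosome 17. That at 125 to 130 Mb on chromosome 8 did too. The intervals of the other dense windows reached 23.2%, so the share decides nothing for them singly. All these intervals treat the peaks of a window as independent, which neighbouring peaks are not. They were also not adjusted for the number of windows, which were chosen after the data had been seen. A share below 23.2% is therefore no firm result for any single window. A higher control signal from open chromatin, which free Dam also methylates, was not separated from copy number, and denser binding on top of either stays open.

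Of the 8 peaks wider than 2 kb, 6 were on chromosome Y, 5 of them between 11919688 and 11944187, and the others were on chromosome 18 from 96578 to 100270 and on chromosome 20 from 46185097 to 46187506. Whether the peaks listed on chromosome Y mark binding there was not tested.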
